A study of Arabidopsis thaliana with 2 samples.

How the data were processed

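The series holds 2 single-cell RNA libraries made from the root tips of seedlings of the plant Arabidopsis thaliana, accession Col-0. Per the labels, the seedlings were 6 days old, had grown at 22 °C in continuous light and received either a mock treatment with the solvent DMSO or 10 µM 6-benzylaminopurine (BAP), a synthetic cytokinin, for 2 h. Per the labels' protocols, root tips were then digested for about 1 h into protoplasts, which are plant cells freed of their walls, passed through strainers of 70 and 40 µm and stained with 14 µM DAPI. Cells that excluded the dye were collected on a cell sorter and loaded for droplet capture with a 10x Chromium 3' version 3 kit, in which unique molecular identifiers (UMIs) mark the captured transcripts. There is 1 library in each group, named here the mock library and the BAP library.

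The deposited matrices hold whole-number UMI counts per gene and cell barcode, not normalised, and per the labels they are the filtered matrices of cell barcodes. Cell Ranger and the TAIR10 build are named per the submitters' processing notes, and their version and settings are not given in the sources used here. The files list 34262 genes, of which 33977 are nuclear and 285 lie in the chloroplast or mitochondrial genome. Gene symbols were taken from the files. A reference table of the TAIR10.1 assembly, which held 32548 of the IDs, served only for names and neighbouring genes, and no coordinates are printed because the build of the files is named TAIR10. A symbol shared by several IDs was replaced by the ID.

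Barcodes were kept with at least 1000 UMIs, at least 500 detected genes and at most 10% of UMIs from mitochondrial genes. No barcode fell under the first pair of limits, and 52 mock and 34 BAP barcodes exceeded the third. The doublet caller Scrublet marked 0 mock and 3 BAP barcodes, under the 0.5% of a library set beforehand as the least for its calls to be used; whether doublets had been removed earlier is not given in the sources used here. The barcodes with the highest doublet scores were left out in place of its calls, at 0.8% per 1000 barcodes, which removed 1061 mock and 763 BAP barcodes. Their median was 3514 and 2495 UMIs, against 3155.5 and 2673 in the cells kept, so those of the BAP library did not hold more UMIs as doublets would. This left 10456 mock and 9002 BAP cells, which held 87.0% and 91.8% of the deposited UMIs.

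For clustering, counts were scaled to 10000 per cell and log-transformed. Organelle genes and genes whose library sums differed over 1.5-fold were left out, 2000 variable genes were ranked within each library, and each gene was centred and scaled within its library. The first 40 principal components, 20 nearest neighbours, a shared-neighbour graph and Leiden clustering at resolution 1 gave 31 clusters. Markers of 13 cell classes had been fixed beforehand. A cluster was named for a class, as "X-like", when its mean log2 fold over the other clusters across that class's markers was at least 0.5 (5 CPM added to both sides) and at least 3 markers of the class were 2-fold higher with at least 10 UMIs. A cluster with more markers of another class among its 10 leading genes stayed unnamed. So would one with no marker there and a median of UMIs per cell far under that of its library. These naming thresholds were set after the data had been seen. They gave 12 classes; no cluster was named for shoot photosynthetic cells. The 13 unnamed clusters, which the thresholds kept out, held 52.0% of mock and 45.9% of BAP cells.

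Counts were summed over all kept cells of a library, and over each class, and divided by the sum over nuclear genes to give CPM, counts scaled to the same nuclear total in every library and class. The comparison is the ratio of CPM, BAP over mock, with an exact conditional binomial (Clopper-Pearson) 95% interval. These intervals cover counting error only. With 1 library per group there is no replicate, so no p-value, standard error or count of changed genes is given, and a ratio describes these 2 libraries. A library at 0 was set to a floor of 3 counts over its sum, which gives a bound on the ratio, although the counting interval of such a ratio reaches nearer to 1; no ratio is given where both libraries are at or under that floor. Shares of cells carry exact binomial 95% intervals. Of each of 24 gene lists, members with at least 20 UMIs in the 2 libraries together count as measured, and the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean CPM in 20 bins, as a description of these libraries. A member is called higher or lower where its interval excludes 1. Classes with under 50 cells in a library were left out of class ratios. Cells with a transcript of the G2 and M phase list were counted after thinning each cell to 1327 UMIs, the 10th percentile, which left out 573 mock and 1372 BAP cells.

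Named genes followed a rule. Over the library they are the 12 genes whose interval bound nearest 1 lies farthest above 1, and the 12 farthest below, among those with at least 100 UMIs in all and 10 CPM in one library. To these the rule adds the members of the type-A regulator, cytokinin degradation, cytokinin synthesis, TMO5/LHW and SHR/SCR lists, and the 2 highest and 2 lowest members of every other list. Within a class they are the 3 genes farthest on each side among those with at least 50 UMIs and 20 CPM. The gene lists, markers, filters, clustering settings, this rule and the alternatives were fixed before the data were examined. The naming thresholds, the 4 class shares treated as main values, 3 further alternatives, the rule for genes that differ in opposite directions between classes, the 4 gene groups of the last part, the ratios in single xylem-like clusters, the shares pooled over clusters and some tests named there were chosen afterwards.

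The alternatives were all deposited barcodes, a minimum of 3000 UMIs, doublets kept, edgeR's TMM factors, DESeq2's median of ratios, a total with organelle genes, the same weight for each cell, the same weight of each cluster in both libraries, other count minima, Leiden resolutions of 0.5 and 2, differing genes kept in the clustering, scaling over both libraries together, cells thinned before summing and, for cells in division, no thinning, the S phase list or at least 2 UMIs. Added after the data had been seen were results without the 100 cells with most UMIs, without a pair of clusters in doubt, and without the single cell with most UMIs of a gene. In classes, TMM factors moved the log2 ratios by 0.27 in trichoblast-like, 0.17 in cortex-like, 0.16 in xylem-like, 0.16 in endodermis-like and 0.11 in phloem companion cell-like cells, and the median of ratios moved them by 0.29 in trichoblast-like and 0.14 in cortex-like, xylem-like and phloem companion cell-like cells. Over the whole library these shifts were 0.04 and 0.05.

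The ratio step was tested on counts simulated from these libraries with genes changed by known folds, over 18939 genes. The counts were Poisson draws from the pooled libraries, the error that the interval assumes, without any spread between cells. They check the calculation and cannot show how well the intervals cover the error in these data. The interval held the true ratio for 95.3% of 18731 unchanged genes. Of 60 genes simulated 4-fold higher, which included the type-A list, 100% had an interval wholly above 2; of 48 simulated 4-fold lower, 97.9% had one wholly below 0.5; at 1.5-fold this was 0% in both directions. Of 23 unchanged lists, 2 had medians outside the 2.5th to 97.5th percentile, and the list simulated 4-fold higher stood at percentile 100. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.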

Results

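Root tips of Arabidopsis seedlings were profiled cell by cell after 2 h with 10 µM of the cytokinin BAP or with DMSO, with 1 library for each. The mock library held 11569 barcodes and 116752936 UMIs and the BAP library 9799 barcodes and 115831629 UMIs, with a median of 3157 and 2641 UMIs per barcode. After filtering, the 10456 mock and 9002 BAP cells held a median of 1840 and 1626 detected genes. UMIs were spread unevenly: the 1000 cells with most UMIs held 54.3% of the mock and 61.2% of the BAP UMIs. Ratios below are BAP over mock, with 95% counting intervals in parentheses that cover counting error only, and since there was no replicate no difference could be set against the spread between preparations.

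The first question was which transcripts of the root tip differed after a short cytokinin treatment. The type-A response regulators (ARRs), which are direct targets of cytokinin signalling and dampen it, had the highest median ratio of the 24 gene lists fixed beforehand. Transcripts of ARR16 (AT2G40670) numbered 0 in the mock and 2179 in the BAP library and were at least 693-fold higher, with the mock library set to a floor of 3 counts, and 563-fold at the lower bound of the counting interval. Those of ARR15 (AT1G74890) were 175-fold higher (80.1 to 478), from 6 to 1100 UMIs, and ARR5 (AT3G48100), the most abundant member after treatment at 371 CPM, was 10.6-fold higher (10.3 to 11.0). In the opposite direction, small heat shock protein genes were lower in the BAP library, and so were genes of the cell cycle and of the TMO5/LHW module that controls divisions in the young vascular tissue.

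Of 18945 nuclear genes with at least 100 UMIs in both libraries together, 91.5% had a ratio between 0.5 and 2, and the median log2 ratio was −0.053. The interval lay wholly above 2 for 891 genes and wholly below 0.5 for 281 genes, which describes these libraries and is no count of changed genes.

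**Figure D1:**
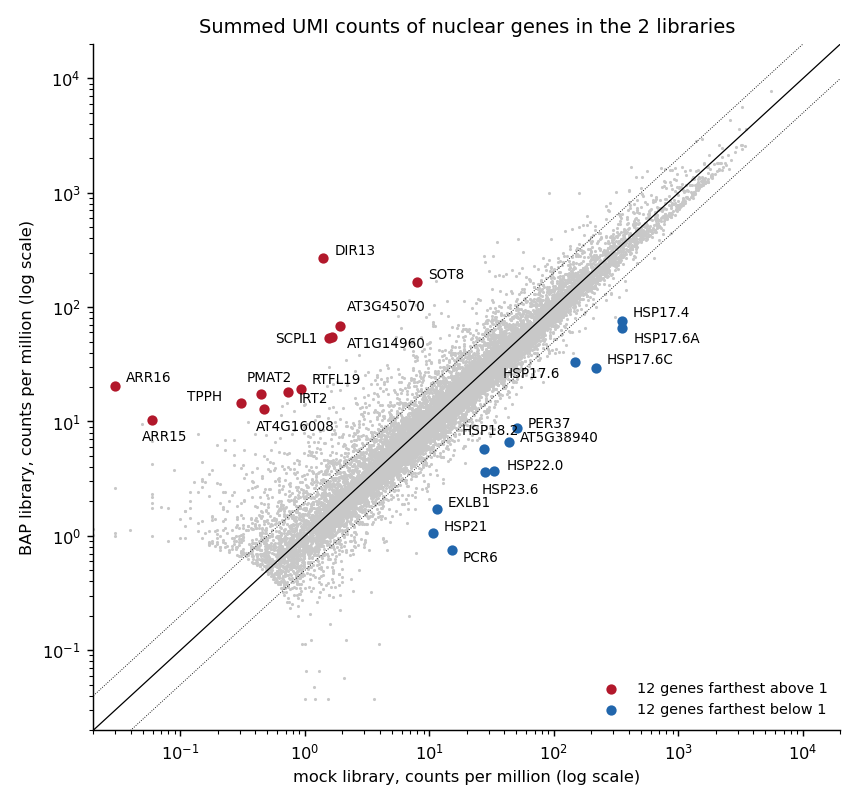
Each point is a nuclear gene with at least 100 UMIs in both libraries together, placed by its CPM in the mock library (horizontal, log scale) and in the BAP library (vertical, log scale), and the dotted lines mark 2-fold differences. ARR16, with 0 UMIs in the mock library, is drawn there at the floor of 3 counts (0.0297 CPM).

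All 10 type-A regulators were higher in the BAP library, with a median log2 ratio of 3.14 that stood at percentile 100 of random lists matched on expression. ARR3 (AT1G59940) was 9.54-fold higher (8.97 to 10.2), ARR6 (AT5G62920) 8.14-fold, ARR7 4.71-fold and ARR4 3.79-fold. ARR8, at 2.83-fold, and ARR9, at 2.51-fold (2.38 to 2.65), were nearest to 1. ARR17 rested on few molecules, 3 in the mock and 106 in the BAP library, with a ratio of 33.7 (11.2 to 166) that became 794 with each cell given the same weight. The type-B regulators, the transcription factors that act upstream of the type-A genes, had a median log2 ratio of 0.14 (percentile 81.2). Of their 7 members 4 were higher, led by ARR12 at 1.56 and ARR14 at 1.45, and 2 were lower, ARR11 at 0.498 and ARR10 at 0.807.

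Genes that remove cytokinin were mostly higher. Of 8 measured genes of degradation and conjugation 6 were higher and 1 lower, with a median log2 ratio of 1.2 (percentile 100). The cytokinin oxidase CKX3 (AT5G56970) was 13.4-fold higher (11.4 to 15.9), CKX5 4.52-fold (6.94-fold with equal cluster weights), the glycosyltransferase UGT85A1 2.89-fold, CKX7 2.32-fold, CKX6 2.27-fold and UGT76C2 1.46-fold. UGT76C1 had a ratio of 1.13 (0.988 to 1.303), and CKX4 (AT4G29740) was lower at 0.277 (0.241 to 0.317), or 0.439 with each cell given the same weight. CKX1 and CKX2 had too few UMIs to be measured. Among 9 receptors and phosphotransfer proteins 7 were higher and 1 lower, with a median of 0.45 (percentile 99.7). AHP4 was 7.0-fold higher (4.55 to 11.2; 4.56 with equal cluster weights) and AHP1 3.47-fold, whereas AHP5 had a ratio of 0.936 and AHP6, an inhibitor of the pathway, was lower at 0.224.

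Genes of cytokinin synthesis and activation diverged. Of 15 members 3 were higher and 8 lower, with a median of −0.24 (percentile 4.28). Of the hydroxylases that make trans-zeatin, CYP735A2 (AT1G67110) was 30.3-fold higher (20.01 to 48.0) and CYP735A1 4.45-fold. LOG2 had a ratio of 19.6 (5.08 to 167) on 2 and 41 UMIs, ranging from 11.6 to 65.8 across settings. The activating enzymes LOG3 at 0.343 (0.535 with equal cluster weights), LOG1 at 0.472, LOG4 at 0.533 (0.941 with equal cell weights) and LOG7 at 0.848 were lower, as were the isopentenyltransferases IPT1 at 0.332 (0.186 to 0.573 under other weights), IPT7 at 0.540, IPT5 at 0.725 and IPT9 at 0.873. IPT2 at 0.921, IPT3 at 1.03, LOG5 at 0.477 and LOG8 at 1.01 had intervals that held 1. The 6 cytokinin response factors were split evenly, 3 higher and 3 lower, with a median of 0.10 (percentile 82.2); CRF6 had a ratio of 1.61, CRF4 1.39, CRF2 0.604 and CRF1 0.576.

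Outside these lists, among genes with at least 100 UMIs in all and 10 CPM in one library, the highest ratios belonged to the dirigent protein gene DIR13 (AT4G11190), 190-fold higher (161 to 226), the trehalose phosphatase gene TPPH, 47.5-fold (33.3 to 70.2), the acyltransferase gene PMAT2, 38.8-fold (28.8 to 53.3), and AT3G45070, 36.3-fold (31.4 to 42.1). SCPL1, AT1G14960, AT4G16008, IRT2, SOT8 and RTFL19 lay between 34.6-fold and 20.6-fold. Equal cell or cluster weights lowered several of these, DIR13 to 79.8, PMAT2 to 24.5, SCPL1 to 21.5, AT1G14960 to 21.1, SOT8 to 13.8, RTFL19 to 12.9 and IRT2 to 11.5. A single cell held 64.5% of the 31 mock UMIs of TPPH and 40.5% of those of AT1G14960. Lowest under the same limits were PCR6 (AT1G49030) at 0.0499 (0.0393 to 0.0625), the expansin-like EXLB1 at 0.150, AT5G38940 at 0.152 and the peroxidase PER37 at 0.172, which was 0.0928 with equal cell weights; 1 cell held 36.3% of the BAP UMIs of EXLB1.

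The other 8 of the 12 lowest genes encode small heat shock proteins, from HSP21 (AT4G27670) at 0.0998, HSP22.0 at 0.112, HSP23.6 at 0.129 and HSP17.6C at 0.137 to HSP17.6A at 0.184, HSP18.2 at 0.211, HSP17.4 at 0.218 and HSP17.6 at 0.227. All 8 members of the heat shock list were lower, with a median of −1.86 (percentile 0.00), among them HSP90.1 at 0.348, HSP101 at 0.369, HSP70 at 0.436 and HSFA2 at 0.506. Several of the small proteins have similar copies, and how the deposited counts divided reads between them is not given in the sources used here. Genes induced early by wounding and jasmonate had a median of −0.21 (percentile 6.40), with 4 of 14 higher and 8 lower; WRKY53 had a ratio of 1.33, WRKY33 1.303, JAZ10 0.725 and JAZ8 0.519.

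Auxin genes differed in part. Of 17 Aux/IAA repressors 12 were higher and 3 lower, with a median of 0.39 (percentile 99.96); IAA5 (AT1G15580) was 12.2-fold higher (10.5 to 14.2; 8.07 with equal cluster weights) and IAA3, a known target of cytokinin signalling in roots, 4.38-fold, and the lowest were IAA29 at 0.840 and IAA6 at 0.877, which was 1.67 with equal cell weights. Auxin transporters went the other way, 8 of 12 lower and 4 higher with a median of −0.26 (percentile 1.50); LAX1 had a ratio of 0.591 and LAX3 0.514, against 1.91 for ABCB4 and 1.53 for PIN4. Of 14 measured ethylene genes 9 were higher and 2 lower, with a median of 0.37 (percentile 99.88), led by ARGOS at 6.88 and the synthase ACS5 at 4.35; ERF1 was lower at 0.474 (0.797 with equal cell weights) and ACS6 had a ratio of 0.963, which turned to 1.103 with equal cell weights.

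Among 13 measured expansins 7 were higher and 5 lower, with a median of 0.30 (percentile 99.6). EXPA18 at 3.85 and EXPA7 at 3.33, which are markers of root hair cells, had ratios of 1.72 and 1.48 with equal cluster weights, and the share of trichoblast-like cells was also higher in the BAP library (2.60-fold). That share leaves out the unnamed cluster 10, which carries trichoblast markers and with which the ratio was 0.955. EXPA1 at 0.483 and EXPA17 at 0.417 were lower. The iron uptake list was near 0 at 0.044 (percentile 64.9), a median that turned to −0.14 with equal cell weights, with 1 of 6 members higher, BHLH101 at 1.203 (0.939 with equal cell weights), and 2 lower, the transporter IRT1 at 0.107 (0.3002 with equal cell weights) and its regulator FIT at 0.312; BHLH38 had a ratio of 1.36 (2.34 with equal cell weights). Of 7 other nutrient and sodium transporters 3 were higher and 4 lower, with a median of −0.081 (percentile 42.8); NRT2.1 had a ratio of 34.4 (9.17 to 289) on 2 and 72 UMIs, 65.5 without a pair of clusters in doubt and 20.7 with equal cluster weights, HKT1 2.90 (1.58 with equal cluster weights), NRT1.1 0.671 and PHT1;1 0.619.

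Photosynthesis genes, listed as markers of shoot cells, had a median of 0.84 (percentile 99.5), with 5 of 6 measured members higher. LHCB2.1 was 8.04-fold higher (5.73 to 11.6) on 38 and 320 UMIs and RBCS1A 2.19-fold, LHCA1 had a ratio of 1.53 and LHCB1.1 of 0.851, which turned to 1.72 with equal cluster weights; no cluster was named for shoot cells. The 10 reference genes had a median of −0.057 (percentile 55.2), with 2 higher and 5 lower, between 0.825 for the elongation factor gene AT5G60390 and 0.856 for UBQ10 at the low end and 1.103 for ACT2 and 1.11 for ACT8 at the high end.

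**Figure D2:**
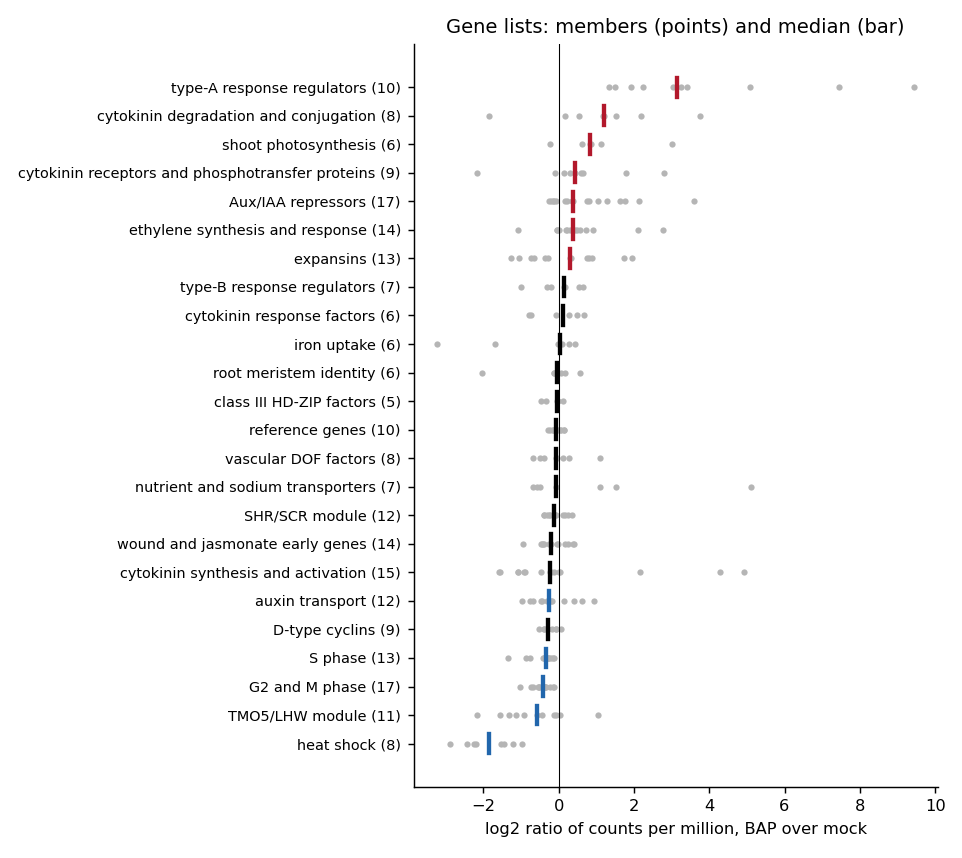
Median log2 ratio (BAP over mock) of each of the 24 gene lists, with red and blue bars for medians above or below the central 95% of random lists matched on expression. The type-A regulators reach 3.14 and the heat shock genes −1.86.

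The second question, from the title of the series, concerned signals that organise vascular development. TMO5 and LHW encode partner transcription factors of young xylem cells whose targets include the cytokinin-activating LOG3 and LOG4. Of 11 genes of this module 8 were lower in the BAP library, 1 was higher and 2 had intervals that held 1, with a median log2 ratio of −0.57 (percentile 0.00) that lay nearer 0, at −0.18, with equal cell weights. AHP6 (AT1G80100) had a ratio of 0.224 (0.190 to 0.264), BHLH144 (AT1G29950, listed as SACL3, an antagonist of the module) 0.404 (0.374 to 0.436), TMO5 (AT3G25710) 0.453 (0.416 to 0.492), BGLU44 0.672 and T5L1 0.733. LHW at 1.03 (0.975 to 1.08) and DOF2.1 at 0.955 (0.906 to 1.01) differed little, and GATA20 was higher at 2.06 (1.86 to 2.29).

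In xylem-like cells, the class named from markers of xylem that include TMO5 and T5L1, TMO5 had a ratio of 0.426 (0.337 to 0.536), LOG3 of 0.270, BHLH144 of 0.285, SHR of 0.477 and LHW of 0.536. The class joins 2 clusters whose mix differed, with cluster 31, which holds little TMO5, at 14.9% of the class in the mock and 25.0% in the BAP library. In cluster 22 alone the ratios were 0.458 (0.362 to 0.577) for TMO5, 0.287 for LOG3, 0.307 for BHLH144, 0.517 for SHR and 0.569 for LHW. T5L1, with 1017 and 876 UMIs there, was nearer to 1 at 0.866 (0.790 to 0.948). Cells of cluster 22 held a median of 3514 UMIs in the mock and 2206.5 in the BAP library. Whether these cells were alike in the 2 libraries was not tested. All 8 measured members were lower in the class, with a median of −1.15 that ranged from −0.53 to −3.13 across clusterings. In procambium-like cells, for which SHR is a naming marker, TMO5 had a ratio of 0.923 (0.805 to 1.06), AHP6 of 0.423, BHLH144 of 0.646 and GATA20 of 2.49, and the median was −0.14 (−0.77 with equal cell weights).

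**Figure D3:**
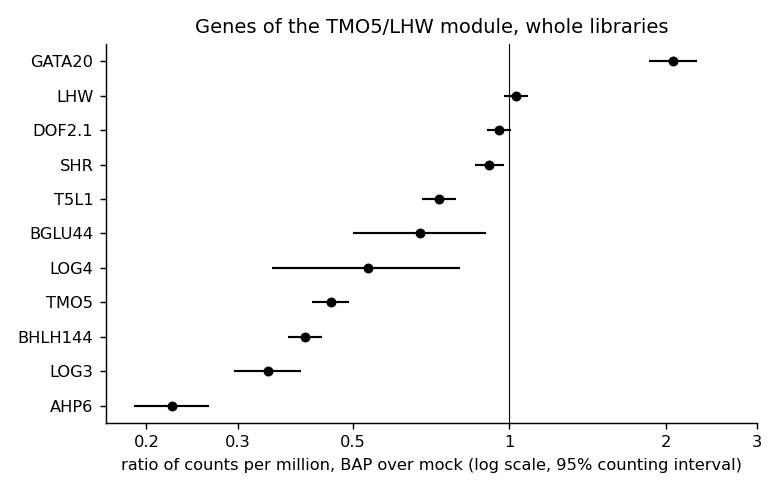
Ratio of CPM, BAP over mock (log scale), of each gene of the TMO5/LHW module over the whole libraries, with 95% counting intervals. AHP6 lies lowest at 0.224 and GATA20 highest at 2.06.

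SHR, a transcription factor that moves from the vascular tissue into the endodermis, had a ratio of 0.915 (0.858 to 0.976), which turned to 1.17 with equal cell weights and 1.31 with equal cluster weights. Of 12 genes of the SHR/SCR module 3 were higher and 5 lower, with a median of −0.12 (percentile 24.0) that became 0.028 with equal cluster weights. SCR had a ratio of 0.766, CYCD6;1 0.769, SCL3 0.807 (1.00 with equal cell weights) and NUC 0.856; MGP at 0.932, JKD at 0.9495, AtIDD11 at 0.845 and SCL23 at 1.13 had intervals that held 1, and MYB36 at 1.08, SNE at 1.19 and AT1G14580 at 1.28 were higher. The vascular DOF factors had a median of −0.061 (percentile 45.4; 0.043 with equal cluster weights), with 3 of 8 higher and 3 lower; HCA2 had a ratio of 2.15, DOF2.2 1.22, DOF2.4 0.707 and OBP2 0.621. The class III HD-ZIP factors had a median of −0.046 (percentile 51.7) that turned to 0.005 under the median of ratios and to 0.25 with equal cell weights, with 2 of 5 lower, PHB at 0.797 (1.07 with equal cell weights) and REV at 0.717, and ATHB-8 at 0.986.

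Root meristem genes had a median of −0.030 (percentile 54.6), which turned to 0.006 under TMM scaling, 0.02 under the median of ratios and 0.15 with equal cluster weights; 2 of 6 were higher, PLT3 at 1.47 and PLT1 at 1.13, and 2 lower. WOX5 (AT3G11260), the regulator of the quiescent centre, was lower at 0.244 (0.164 to 0.354) on 141 and 36 UMIs, and ARF5 had a ratio of 0.912. In quiescent centre and initials-like cells the ratio of WOX5 was 0.233 (0.0776 to 0.589). WOX5 is a listed marker of this class, but it was not among the 3 that met the naming limits there, PLT1, PLT2 and BBM.

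The third question was which cells carried the response. Type-A transcripts summed over the 10 genes were higher in the BAP library in all 12 named classes, with ratios from 4.45 to 9.51. The ratio was 9.51 (8.42 to 10.8) in phloem companion cell-like cells, 1.67 times (1.48 to 1.89) that of all other cells, 7.04 (5.89 to 8.50) in cortex-like and 6.92 (5.06 to 9.65) in endodermis-like cells, the latter on 46 mock UMIs and 1.2 times (0.880 to 1.64) that of all other cells. The cortex-like class had a different share in each library, so its cells may not be alike in the 2 libraries. The ratio was 4.88 in xylem-like and 4.45 (4.32 to 4.58) in root cap-like cells, the latter 0.728 times (0.703 to 0.754) that of all other cells. These intervals treat each UMI as independent and leave out the spread between cells, so they are too narrow for setting classes apart. For the split of UMIs among the 10 genes, the limit in phloem companion cell-like cells was 0.0294 from draws of UMIs and 0.0527 from draws of cells. The level after BAP ran from 474 CPM in atrichoblast-like to 2073 CPM in quiescent centre and initials-like cells. ARR5 supplied more type-A UMIs than any other member in 11 classes and ARR4, with 29.3%, in xylem-like cells; ARR16 made up 6.96% in pericycle-like and 0.05% in root cap-like cells.

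**Figure D4:**
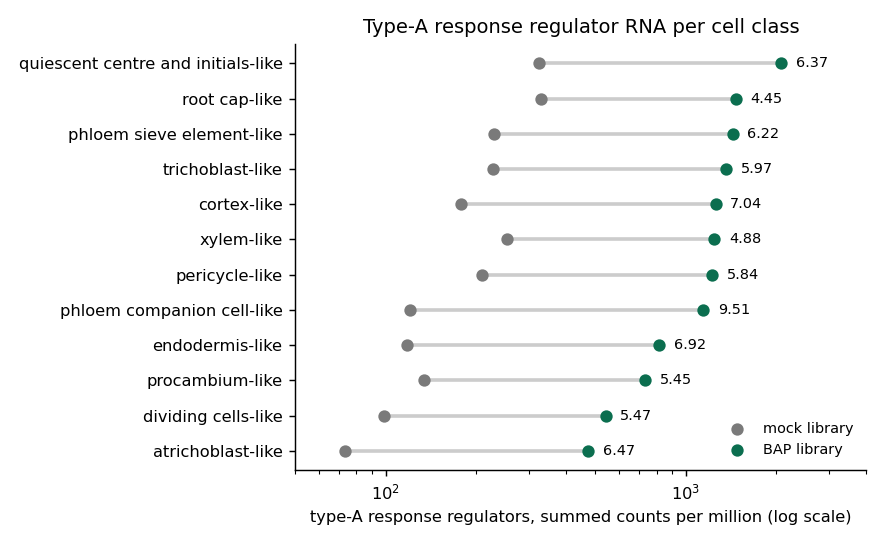
Type-A UMIs summed over 10 genes in each named class, in CPM in the mock and BAP libraries, with the ratio printed beside each pair. The ratio is highest in phloem companion cell-like cells (9.51) and lowest in root cap-like cells (4.45).

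The genes farthest from 1 were also picked within each class, and differences between classes were not tested for them. In pericycle-like cells DIR13 had a ratio of 591 (163 to 4884) on 2 mock UMIs, with values from 308 to 972 across settings. ARR16 was at least 106-fold higher there (at least 21.4-fold after thinning). CKX3 had a ratio of 85.6 (28.9 to 418) there on 3 mock UMIs, with values or lower bounds from 18.1 to 197 across settings. In endodermis-like cells DIR13 was 125-fold (57.3 to 343) and SOT8 35.2-fold higher (22.1 to 59.8), and in phloem companion cell-like cells DIR13 was at least 131-fold higher (at least 18.7-fold after thinning). SOT8 was not among the picks in phloem companion cell-like cells and belongs to a gene group chosen after its values had been seen. It was 59.7-fold higher there (20.2 to 292), on 3 mock UMIs. In phloem companion cell-like cells the glutaredoxin gene GRXS5 had a ratio of 164 (63.7 to 603) on 4 mock UMIs. Its values or lower bounds ran from 30.0 to 296 across settings. In procambium-like cells ARR5 had a ratio of 8.98 (8.02 to 10.1), below its 10.6 over the whole library, and AT1G49500 one of 9.13 (7.501 to 11.2), with values from 3.35 to 16.4 across settings, and in quiescent centre and initials-like cells AT2G39980 had one of 40.4 (23.9 to 74.3). IAA5 in xylem-like cells had a ratio of 161 (28.6 to 6413) on 1 mock UMI, with values or lower bounds from 6.54 to 596 across settings. Among the lowest, BCAT7 in root cap-like cells had a ratio of 0.00681 (0.00140 to 0.0201) on 328 and 3 UMIs. Its values or upper bounds ran from 0.00375 to 0.213 across settings. SBP3 in xylem-like cells had a ratio of 0.0936 (0.0616 to 0.137), with values from 0.0417 to 0.171 across settings. PER49 in endodermis-like cells was at most 0.0221, with 0 BAP UMIs, or at most 0.126 after thinning. Several other low values rested on 1 mock cell, which held 99.6% of the UMIs of AT4G38080 in endodermis-like, 99.0% of RTNLB14 in procambium-like and 87.8% of NEN4 in phloem sieve element-like cells.

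The last question was whether the make-up of the root tip differed. Shares of cells can be set by the sort on DAPI exclusion and by the gap in UMI depth between the libraries. Trichoblast-like cells made up 2.78% of the mock and 7.23% of the BAP cells, a ratio of 2.60 (2.26 to 2.99), and cortex-like cells 1.82% and 4.99%, a ratio of 2.75 (2.31 to 3.27). With at least 3000 UMIs per cell in the clustering these ratios were 4.48 and 4.29. Unnamed clusters near to these classes went the other way. Cluster 10, which carries the trichoblast markers COBL9, RHD6 and RSL4, scored 0.497 for trichoblast, just under the limit of 0.5 set after the data had been seen. It held 6.40% of mock and 1.53% of BAP cells. Clusters 6, the trichoblast-like one, and 10 together had a ratio of 0.955 (0.868 to 1.05), so the ratio of 2.60 rests on cluster 10 staying unnamed. The 4 clusters that scored highest for cortex, 3 of them unnamed, together had a ratio of 1.16 (1.06 to 1.27). Dividing cell-like cells made up 3.38% and 2.28%, a ratio of 0.675 (0.565 to 0.803), and procambium-like cells 6.11% and 3.42%, a ratio of 0.560 (0.487 to 0.642). The 3 clusters that scored highest for procambium, 2 of them unnamed, together had a ratio of 0.673 (0.609 to 0.744). Cluster 5, the procambium-like one, scored 0.596 for procambium and 0.555 for quiescent centre and initials. Under 3 other clusterings no cluster met the rule for procambium.

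Atrichoblast-like cells had a ratio of 1.21, or 1.94 at Leiden resolution 2, quiescent centre and initials-like cells 1.197 (0.959 to 1.49), endodermis-like 1.15, phloem companion cell-like 1.14, root cap-like 1.05, xylem-like 1.03, or 1.60 at both other resolutions, phloem sieve element-like 1.01, or 2.49 (1.29 to 4.99) among cells with at least 3000 UMIs, and pericycle-like 0.893 (0.794 to 1.00). In total, 10.6% (9.58 to 12.1) of cells would have to change class for the shares to be equal, with all unnamed clusters counted as a single class whose share was 52.0% in the mock and 45.9% in the BAP library. Much of the value is thus exchange with unnamed cells. The unnamed cluster 27, led by histone genes, held 1.59% of mock and 0.378% of BAP cells.

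**Figure D5:**
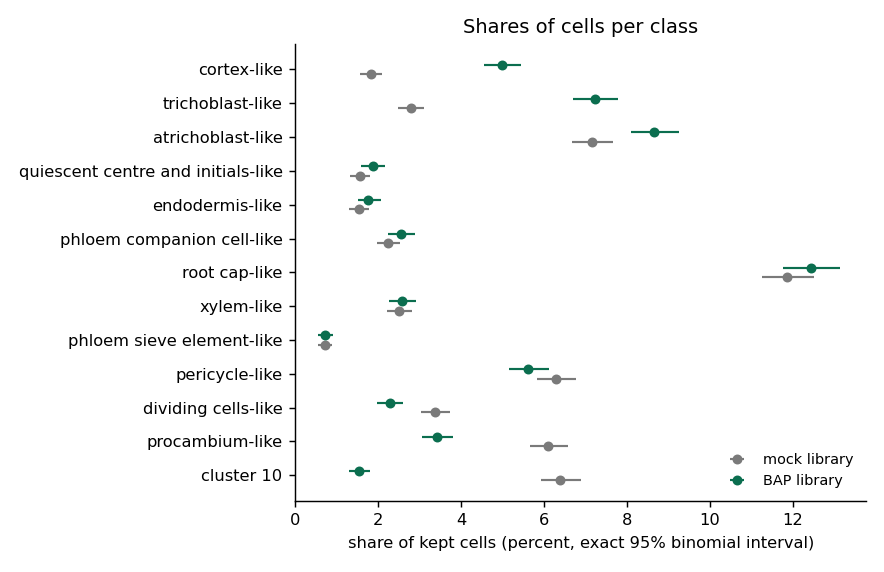
Share of kept cells (percent) in each named class and in the unnamed cluster 10, which carries markers of trichoblasts, in the mock and BAP libraries, with exact 95% binomial intervals. Trichoblast-like and cortex-like shares are higher in the BAP library and procambium-like and dividing cell-like shares and that of cluster 10 lower. Cluster 10 scored 0.497 for trichoblast against a limit of 0.5, and together with the trichoblast-like cluster 6 it had a ratio of 0.955.

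Cell cycle transcripts were lower in the BAP library as well. All 13 S phase genes were lower, with a median of −0.32 (percentile 0.14), from TSO2 at 0.398 and PCNA1 at 0.552 to MCM7 at 0.909 and RNR2A at 0.921, which turned to 1.08 with equal cell weights. Of 17 G2 and M phase genes 16 were lower, with a median of −0.41 (percentile 0.00), from CYCA1;1 at 0.492 and CDKB1;2 at 0.597 to KNOLLE at 0.905, which turned to 1.11 with equal cluster weights, and CYCB2;2 at 0.923. Within dividing cell-like cells, named in part by these genes, the G2 and M phase median was 0.12, and −0.062 with equal cell weights. Of 9 D-type cyclins 4 were lower and none was higher, with a median of −0.28 (percentile 3.53); CYCD5;1 had a ratio of 0.701, CYCD3;3 0.762, CYCD1;1 0.952 and CYCD3;1 1.05.

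After thinning, 15.9% (15.2 to 16.6) of mock and 11.2% (10.5 to 11.9) of BAP cells held a G2 and M phase UMI, against 33.9% and 27.3% unthinned. Trichoblast-like cells gave 15.9% and 10.5%, root cap-like cells 6.14% and 4.83%, and dividing cell-like cells 93.4% and 88.4%. Shares hardly differed in xylem-like cells, at 9.92% and 9.85%, and endodermis-like cells, at 15.9% and 16.3%. All other named classes had a lower share in the BAP library. The trichoblast-like pair leaves out cluster 10, so it may compare unlike cells. Whether a single G2 and M phase UMI marks a cell in division was not tested, and the shares were not read as shares of dividing cells. With at least 2 UMIs they were 4.29% and 2.69% over all cells, 2.09% and 1.83% in trichoblast-like and 78.5% and 70.4% in dividing cell-like cells. Only pericycle-like cells then had a higher share in the BAP library among the named classes, 1.47% and 1.59%.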

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

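In this part the rule that picked genes differing in opposite directions between classes was set after the data had been seen. So were the tests of free RNA and of BAP treatment for the type-A regulators, of the mix of classes and of handling for the heat shock genes, and of both regroupings and of root length or recovery for the shares; the other tests were set before their results were seen.

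A rule for genes with an interval wholly above 2 in one class and wholly below 0.5 in another gave 3 genes, and the difference between the classes was not tested. RTM3 was at least 42.6-fold higher in the BAP library in xylem-like cells, on 0 and 137 UMIs of which 1 cell held 46.7%. Without that cell it was at least 22.7-fold higher. In phloem companion cell-like cells the ratio of RTM3 was at most 0.0284, where 91 mock UMIs came from 4 cells. HSP22.0 had a ratio of 5.50 (3.67 to 8.53) in xylem-like cells, where 15 BAP cells held its 165 UMIs, and of 0.0357 (0.0182 to 0.0635) in root cap-like cells. AT4G39320 had a ratio of 5.70 (4.92 to 6.63) in xylem-like cells and of 0.0172 (0.00205 to 0.0636) in quiescent centre and initials-like cells, where 8 mock cells held 104 UMIs and 1 of them 51.9%.

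The type-A regulators were higher in the BAP library in each class. RNA set free by other cells as the only source in most classes would give every class the same split of UMIs among the 10 genes, and in 11 of 12 classes, all but endodermis-like, the split in the BAP library lay farther from that of all other cells than the upper limit of the central 95% of draws of whole cells. In trichoblast-like cells 1 cell held 34.1% of the type-A UMIs, and without it the distance of 0.151 was 0.095, under the limit of 0.0996. The mock library already held type-A transcripts in every class, from 73.3 CPM in atrichoblast-like to 330 CPM in root cap-like cells. That RNA alone could make the splits differ, even if free RNA had brought the whole increase. The splits therefore cannot decide on the source of the increase. For a difference in UMI depth as the cause, the lowest median log2 ratio after thinning was 1.43 over 11 classes. The ratios had already been divided by the total of each library and class. Thinning therefore mainly changed the weight of cells and is a weak test of depth. The list stood at percentile 100 of random matched lists while the type-B regulators, with a median log2 ratio of 0.14, stood at percentile 81.2. These values were known before BAP treatment was weighed and add no support for it. A response to BAP and any other difference between the preparations cannot be told apart, because each group was prepared once. Free RNA as a source of the increase in each class also stays open.

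The heat shock genes were lower in the BAP library. A different mix of cell classes is argued against by the median of −1.73 with the same weight of each cluster in both libraries, and a few cells with very many UMIs by the median of −1.57 with each cell given the same weight. A warmer or longer handling of the mock preparation would reach every class, and 0 of the 12 classes had a median at or above 0 in the reported clustering, as an effect of BAP on all cells also allows. In 2 classes this turned: with doublets kept the median was 0.082 in pericycle-like and 0.035 in xylem-like cells, and the latter was 0.11 at Leiden resolutions 0.5 and 2. Handling and treatment cannot be told apart, because each group was prepared once.

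Trichoblast-like and cortex-like cells had larger shares, and cluster 10 a smaller one, in the BAP library. Among cells with at least 3000 UMIs the trichoblast-like ratio was 4.197 (2.60 to 7.02), which rests on 23 mock and 75 BAP cells. A minimum does not make depth equal, so this value cannot decide whether the gap in UMI depth set the trichoblast-like share. Cells of cluster 6 held a median of 1523 UMIs in the mock and 1489 in the BAP library, and those of cluster 10 held 3961 and 2522.5. Depth could therefore bear on which of the 2 clusters a cell joined. Cells of the hair lineage may have been grouped in cluster 6, the trichoblast-like one, in the BAP library and in cluster 10 in the mock library, since both clusters together had a ratio of 0.955 (0.868 to 1.05). For cortex, the 4 clusters that scored highest for it had a ratio of 1.163 (1.06 to 1.27) together, against 2.75 for the cortex-like cluster 13. Since 3 of them were unnamed and the pooled interval lies above 1, a regrouping of cortex cells stays open, and so does a smaller difference in their share. A different length of root or recovery of cells cannot be told apart from treatment, since each group was sampled once. A longer piece of root in the BAP library would need a dividing cell-like ratio below 1, which was 0.675, and ratios above 1 in all classes of elongating and differentiating cells. Of these, pericycle-like had 0.893 (0.794 to 1.00) and phloem sieve element-like 1.01, with intervals that held 1. An uneven recovery of tissues need not give this pattern, so these values cannot decide on it. Among cells with at least 3000 UMIs pericycle-like had 1.11 and phloem sieve element-like 2.49, while xylem-like had 0.874 (0.678 to 1.123) and endodermis-like 0.965 (0.521 to 1.762).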

How the results depend on the processing

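Of the tests here, those without the 100 cells with most UMIs, without a pair of clusters in doubt and without the top cell of a gene were chosen after the results were seen. No paired analysis was possible because each group holds 1 library. Every deposited barcode gave no results by class, since cells outside the clustering have none, and splits of the samples could not be compared. Of 1480 values for 148 genes 12 reversed, of 779 for 72 genes in classes 2, of 264 list medians 1, of 395 list medians in classes 8, and of 74 values for shares 0; reversal was counted where the counting interval of the reported value excluded 1, or 0 for a log2 median. Genes wholly above 2 numbered 891, and from 677 with equal cluster weights to 1057 from 20 UMIs on; genes wholly below 0.5 numbered 281, and from 251 with the median of ratios to 337 from 20 UMIs on. No cluster met the naming rule for procambium with differing genes kept, with both libraries scaled together or with doublets kept. ARR17, at 33.7 on 3 mock UMIs, had 794 with each cell given the same weight; LOG2, with 65.8 at most, and NRT2.1, with 65.5 at most, stayed within their counting intervals. The cause was not tested for any value that follows.

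With each cell given the same weight, the median log2 ratio was 2.83 for type-A regulators and −0.18 for the TMO5/LHW module, and ratios were 1.17 for SHR, 1.00 for SCL3, 1.07 for PHB, 1.103 for ACS6, 1.08 for RNR2A and 0.939 for BHLH101. The G2 and M phase median was then −0.062 in dividing cell-like and −0.14 in procambium-like cells, and the type-A median 2.83 in phloem companion cell-like cells. With equal cluster weights the medians were 2.78 for type-A regulators, −0.19 for TMO5/LHW and 0.028 for SHR/SCR, and ratios were 1.31 for SHR, 1.03 for SCL3, 1.07 for RNR2A, 1.11 for KNOLLE and 0.965 for BHLH101; without the 100 cells with most UMIs KNOLLE had 1.04.

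With at least 3000 UMIs per cell the type-A median was 3.20, and 3.49 in phloem companion cell-like cells; HSP18.2 in atrichoblast-like cells had a ratio of 1.3, and the ratios of shares were 4.29 for cortex-like and 4.48 for trichoblast-like cells. The percent of cells that would have to change class was then 12.6, and 12.5 at Leiden resolution 2, 13.3 with differing genes kept and 14.3 with both libraries scaled together. The cortex-like ratio was 2.13 with differing genes kept and the procambium-like ratio 0.676 at resolution 0.5. With doublets kept, the type-A median was 3.54 in phloem companion cell-like and 2.07 in root cap-like cells, and the heat shock median 0.082 in pericycle-like and 0.035 in xylem-like cells, the latter 0.11 at resolutions 0.5 and 2. Scaling both libraries together gave type-A 2.77 in phloem companion cell-like and G2 and M phase 0.23 in atrichoblast-like cells, and resolution 0.5 gave G2 and M phase −0.049 in procambium-like cells. After thinning, the type-A median was 1.43 in root cap-like cells. LTP2 in procambium-like cells, with 266 mock and 2 BAP UMIs before thinning, was then at most 1.31, a bound set by the floor. It was counted among the 2 reversals of genes in classes, although an upper bound above 1 shows no reversal. The ratio of cells with a G2 and M phase UMI was 0.703, and 0.806 without thinning and 0.626 from 2 UMIs on.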

Other observations

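The gene groups of this part were picked after their values had been seen, and no tests of explanations were run on them. Genes of thalianol synthesis, neighbours that make a root triterpene, were higher in the BAP library. THAS1 (AT5G48010), the synthase, was 16.8-fold higher (15.5 to 18.1), CYP708A2 15.0-fold, AT5G47980 10.9-fold and CYP705A5, the most abundant at 278 CPM in the BAP library, 10.2-fold. In root cap-like cells THAS1 and CYP708A2 were both 15.1-fold higher, or 9.51-fold and 9.75-fold with each cell given the same weight, and in cortex-like cells they had ratios of 37.4 (20.8 to 75.1) and 48.8 (22.4 to 133), which were 22.6 and 28.2 with each cell given the same weight. The genes of marneral synthesis, a separate group on the same chromosome, had ratios of 9.48 for MRN1, 3.30 for CYP71A16 and 1.52 for CYP705A12.

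A tandem array of glutaredoxin genes was also higher, with GRXS5 at 191 (81.6 to 590) on 5 and 1001 UMIs, GRXS4 at 20.9, GRXS7 at 15.6, GRXS8 at 9.24 and GRXS3 at least 7.0-fold on 0 and 22 UMIs. Phloem companion cell-like cells held 761 of the GRXS5 and 1131 of the 1442 GRXS4 UMIs of the BAP library. The copies are nearly identical, so the division of counts among them is uncertain. Of the cytosolic sulfotransferases, SOT8 at 20.9, AT3G45070 at 36.3 and AT3G45080 at 7.23 were higher, while STO9, the neighbour of SOT8, had a ratio of 1.04 (0.919 to 1.18). Organelle transcripts took smaller shares of UMIs in the BAP library, with a ratio of 0.901 for chloroplast and 0.829 for mitochondrial genes.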
